A study of Mus musculus with 4 samples.

How the data were processed

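The series holds 4 ChIP-seq libraries from wild-type 129 Sv/Ev mice: a BRDT immunoprecipitate and an IgG control from pachytene spermatocytes, and the same pair from round spermatids. Each combination of cell type and antibody has 1 library, so no group has replicates. Per the labels' protocols, the pachytene material was a suspension of whole seminiferous tubule cells from mice of 18 days. It also held spermatogonia, earlier spermatocytes and some Sertoli cells. The round spermatids came from 7 adult mice, were separated by sedimentation through a BSA gradient, and were at least 90% pure by DNA content. Age and purification therefore differ between the 2 cell types along with the stage.

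The files used here are 2 deposited lists of enriched regions, 1 for each BRDT library; no file of the IgG libraries was analysed here. The submitters' processing notes name Bowtie and SICER and the mouse genome build mm8, without versions. Per the file headers, the regions are SICER peaks, and the file names carry a tag read here as a false discovery rate of 10%. SICER joins neighbouring windows with more reads than chance into islands, which suits broad signals and yields regions rather than summits. The window and gap settings, the fragment size, the read filters and the role of the IgG libraries are not given in the sources used here. The lists were deposited per cell type, and whether material from several mice was pooled before sequencing is not given for each library.

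Each deposited list has 3 columns, the chromosome, the start and the end of each island, as positions in base pairs. No score, read count, fold enrichment or FDR per island is given. Every start in both lists is 1 above a multiple of 200 bp and every end is a multiple of 200 bp. Positions were therefore read as 1-based and inclusive, and the width of an island is its end minus its start plus 1. The smallest gap between neighbouring islands is 600 bp in both lists. Read depth is unknown for all 4 libraries, and no read-based interval or floor could be given. Intervals below cover counting error in the number of islands only.

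No annotation of mm8 was used here, and coordinates were not moved between builds. No gene is therefore named from an island, and the planned sorting of islands into promoters, exons, introns and intergenic sequence, with the gene lists fixed for it, was not made.

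Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. An island counted as shared when it overlapped an island of the other list by at least 1 bp. The overlap was set against 100000 random circular shifts of one list against the other within each chromosome, on the 200 bp grid. Each chromosome was taken to run from position 1 to the last island end in either list. This test has a one-sided p-value, and the smallest it can give is 1e-05. Shares of islands per chromosome were compared between the lists by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 21 chromosomes. Densities are islands per Mb of the same span, with exact Poisson 95% intervals, and shares have exact Clopper-Pearson 95% intervals. The number of islands per 1 Mb window was correlated between the lists over the autosomes and X, with p-values from circular shifts of the windows. Island midpoints set the window, and the partial window at each chromosome end was left out. Widths of shared and other islands were compared within each list by a permutation test with 100000 resamples, two-sided.

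All of these tests compare 2 lists from 1 library each. Their p-values concern these lists and not the stages, since the spread between libraries of the same stage is unknown.

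The regions named in the text were chosen by a rule fixed before the data were examined, as were the main tests and most alternatives. The binomial tests of X density and of single windows, and the correlation of widths within pairs, were not among the tests fixed then. Other tests added later are named as such where their values are given. With no value per island in the lists, the rule ranks islands by width. It takes the 6 widest islands of each list, the 6 overlapping pairs with the best mean rank, and the 5 widest islands of each list with none of the other list within 10 kb. It also takes the 5 windows of 1 Mb with the most islands in each list, the 3 widest islands on X in each list, and the islands on Y where a list has 10 or fewer. Regions named outside this rule are said to be chosen after their values were seen. Alternatives covered the definition of overlap, shifts limited to 1 Mb, the 2726 and 2809 widest islands in place of a stricter FDR, equal list lengths, joining of islands closer than 5 kb or 100 kb, and window sizes of 500 kb and 5 Mb.

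The tests were tried on simulated lists with the widths and chromosomes of the real ones. Of 100 pairs of lists of 5452 and 5618 islands placed at random, 2% gave an overlap p below 0.05. With 100 or 400 islands planted in both lists, all of 20 simulated pairs passed, and the median excess over the shifts was 96.1 and 390.1 islands. The window correlation passed in 6% of 200 random pairs; leaving out the partial windows was decided after a first simulated run. The chromosome comparison made at least 1 call in 3.95% of 2000 random divisions of the 11070 islands; the number of divisions was raised after a first, shorter run was seen. The comparison of mean widths, the only width test tried in this way, passed in 2% of 50 simulated lists with no difference and in all of 50 with a difference of 400 bp. In the overlap and window checks islands were placed at random without clustering, and the chromosome check mixed single islands. These rates therefore do not cover clustered islands, such as those of the real lists.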

Results

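BRDT is a testis-specific bromodomain protein of the BET family, whose members bind acetylated histones. Its chromatin occupancy was profiled by ChIP-seq in mouse pachytene spermatocytes, the cells in the long middle stage of meiotic prophase, and in round spermatids, the haploid cells formed after the meiotic divisions. The design asks where BRDT lies on the genome at each stage and whether the places differ between stages. One BRDT library per stage was available as a list of enriched islands on mm8, with an IgG library per stage as the control. The pachytene list holds 5452 islands and the round spermatid list 5618. All islands of both lists lie on the 19 autosomes, X or Y. Neither list gives a strength or a read count per island, and read depth is unknown, so places and widths could be compared but not levels of binding.

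The lists held similar numbers of BRDT islands, and those of round spermatids were wider. The median width was 2600 bp in pachytene spermatocytes (quartiles 1800 and 3600 bp) and 3200 bp in round spermatids (quartiles 2400 and 4400 bp). The islands covered 16.0 Mb in pachytene spermatocytes, or 0.614% of the span of the chromosomes, and 20.2 Mb or 0.771% in round spermatids, a ratio of 1.26. Islands over 10 kb were few, 37 in the pachytene list (0.679%) and 63 in the round spermatid list (1.12%). Number and width both depend on sequencing depth and on the caller's settings, and with 1 library per stage the difference has no replicate check.

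**Figure D1:**
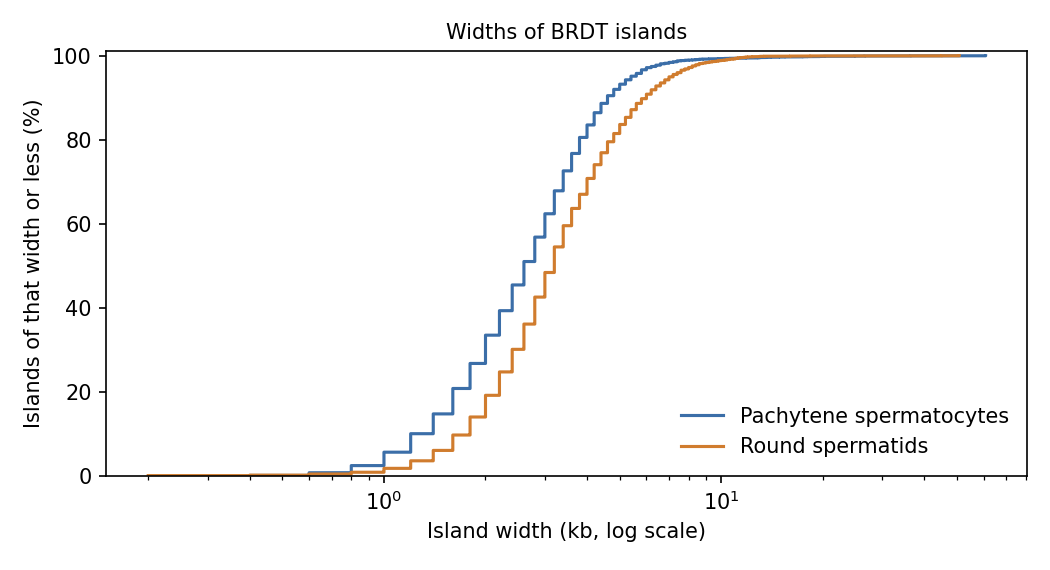
Cumulative share of BRDT islands (y axis, percent) by width (x axis, kb, log scale) in each list. The round spermatid curve lies to the right of the pachytene curve over most of its range, with medians of 3200 and 2600 bp.

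Most BRDT islands of one stage had no counterpart in the other, but the shared ones were far more numerous than chance placement gave. Of the 5452 pachytene islands, 948 were overlapped by a round spermatid island, a share of 17.4% (95% interval 16.4 to 18.4). Conversely, 963 of the 5618 round spermatid islands were overlapped by a pachytene island, a share of 17.1% (95% interval 16.2 to 18.2). Random circular shifts overlapped 79.4 pachytene islands on average (central 95% of shifts 61 to 99, highest 166 of 100000 shifts). The observed number was 11.9 times that mean (circular-shift permutation test, one-sided p = 1e-05, the smallest the shifts can give). Shifts of 20 kb to 1 Mb, which keep the regional density of islands, overlapped 134.7 on average, and the fold against them was 7.04. A total of 4125 pachytene islands (75.7%) and 4222 round spermatid islands (75.2%) had no island of the other list within 10 kb. An island missing from a list did not pass the caller's threshold there, which does not show that BRDT was absent.

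**Figure D2:**
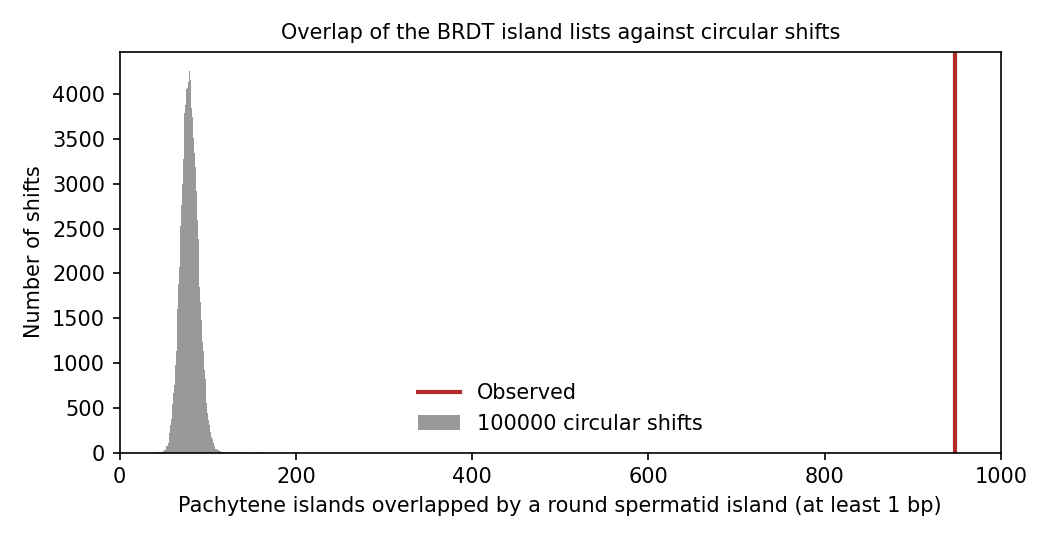
Number of pachytene islands overlapped by a round spermatid island (x axis) in 100000 circular shifts (grey bars, y axis: number of shifts) and as observed (red line). The shifts average 79.4 and reach 166 at most, and the observed number is 948.

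The 948 and 963 shared islands formed 974 overlapping pairs with a median overlap of 2000 bp. The round spermatid island was the wider of the pair in 603 pairs (61.9%), the pachytene island in 326, and 45 pairs had equal widths. The whole round spermatid list is wider too, and whether 61.9% exceeds the share among unrelated islands of these lists was not tested. Only 20 pairs had the same start and end in both lists. Widths within pairs were weakly related across these regions, which are not independent replicates (Spearman's rho 0.22, permutation p = 1e-05, the smallest possible; Pearson's r 0.17, permutation p = 0.00197). Pearson's r was 0.15 without the 2 pairs farthest from the median pachytene width. Shared and other islands had the same median width in each list, 2600 bp in pachytene spermatocytes and 3200 bp in round spermatids (difference of 0 bp, permutation p = 1 in both). The means differed slightly: shared islands were 187 bp wider in the pachytene list (permutation p = 0.00936) and 168 bp wider in the round spermatid list (permutation p = 0.0227). The comparison of means was added after the data were seen. A wider island is more likely to be overlapped by chance, and the permutation does not allow for this. These p-values therefore do not show that shared places are wider for another reason.

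Some of the widest BRDT islands of one list were split into several islands in the other list, and some had no counterpart there. The widest pachytene island spanned 60.8 kb on chromosome 17 from 27017801 to 27078600. In round spermatids the same stretch held 7 separate islands between 27021001 and 27067200. The second widest pachytene island spanned 37.2 kb on chromosome 9 from 67501801 to 67539000, where round spermatids had 5 islands between 67509001 and 67535200. The third, on chromosome 2 from 92362201 to 92398600, was 36.4 kb wide, and the nearest round spermatid island lay 16.2 kb away. A pair of wide pachytene islands were neighbours on chromosome 6. The island from 127743601 to 127776000 (32.4 kb) overlapped a round spermatid island from 127772801 to 127776200, and the island from 127776801 to 127802000 (25.2 kb) overlapped none, the nearest lying 0.6 kb away. The remaining one of the 6 widest lay on chromosome 12 from 98782401 to 98809000 (26.6 kb) and contained a round spermatid island from 98793201 to 98801600.

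In round spermatids the widest island spanned 50.8 kb on chromosome 11 from 3049401 to 3100200, with a neighbour of 18.4 kb from 3030401 to 3048800. The nearest pachytene islands lay 65.8 and 117.2 kb away. The first island of any autosome in either list started at 2999801, so this domain lies close to the first listed position. Next came 45.0 kb on chromosome 1 from 90056601 to 90101600, 1 kb from a pachytene island, and 40.2 kb on chromosome 3 from 25708401 to 25748600. The chromosome 3 island shared its end with a pachytene island of 22800 bp from 25725801 to 25748600, and this was the overlapping pair with the best mean rank in width. The others of the 6 widest lay on chromosome 15 from 78210801 to 78227400 (16.6 kb) and on chromosome 2 from 92171401 to 92187400 (16.0 kb, 2.8 kb from a pachytene island).

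Among overlapping pairs, wide islands met again on chromosome 3 from 3007001 to 3019400 in pachytene spermatocytes and from 3006801 to 3019200 in round spermatids, both 12400 bp wide. This pair, like the chromosome 11 domain, lies close to 2999801, the lowest start listed on any autosome. Whether reads of the IgG control also gather there is unknown, since no IgG file was analysed. On chromosome 1 a pachytene island from 90042601 to 90055600 (13000 bp) met a round spermatid island from 90042601 to 90053800 (11200 bp). On chromosome 7 a pachytene island from 63956601 to 63964000 (7400 bp) met one from 63959201 to 63970600 (11400 bp). The remaining 2 of the 6 best-ranked pairs lay in the chromosome 17 and chromosome 9 domains. After the chromosome 2 domain, the widest pachytene islands with no round spermatid island within 10 kb lay on chromosome 7 from 73658201 to 73678400 (20.2 kb) and chromosome 5 from 150078601 to 150098400 (19.8 kb). A close pair followed on chromosome 10, from 62068601 to 62087000 (18.4 kb) and from 62046401 to 62064000 (17.6 kb), over 70 kb from any round spermatid island. In round spermatids, the widest such islands were the chromosome 11 and 15 domains named above, then chromosome 14 from 59320401 to 59334400 (14.0 kb) and chromosome 2 from 164152801 to 164166000 (13.2 kb).

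**Figure D3:**
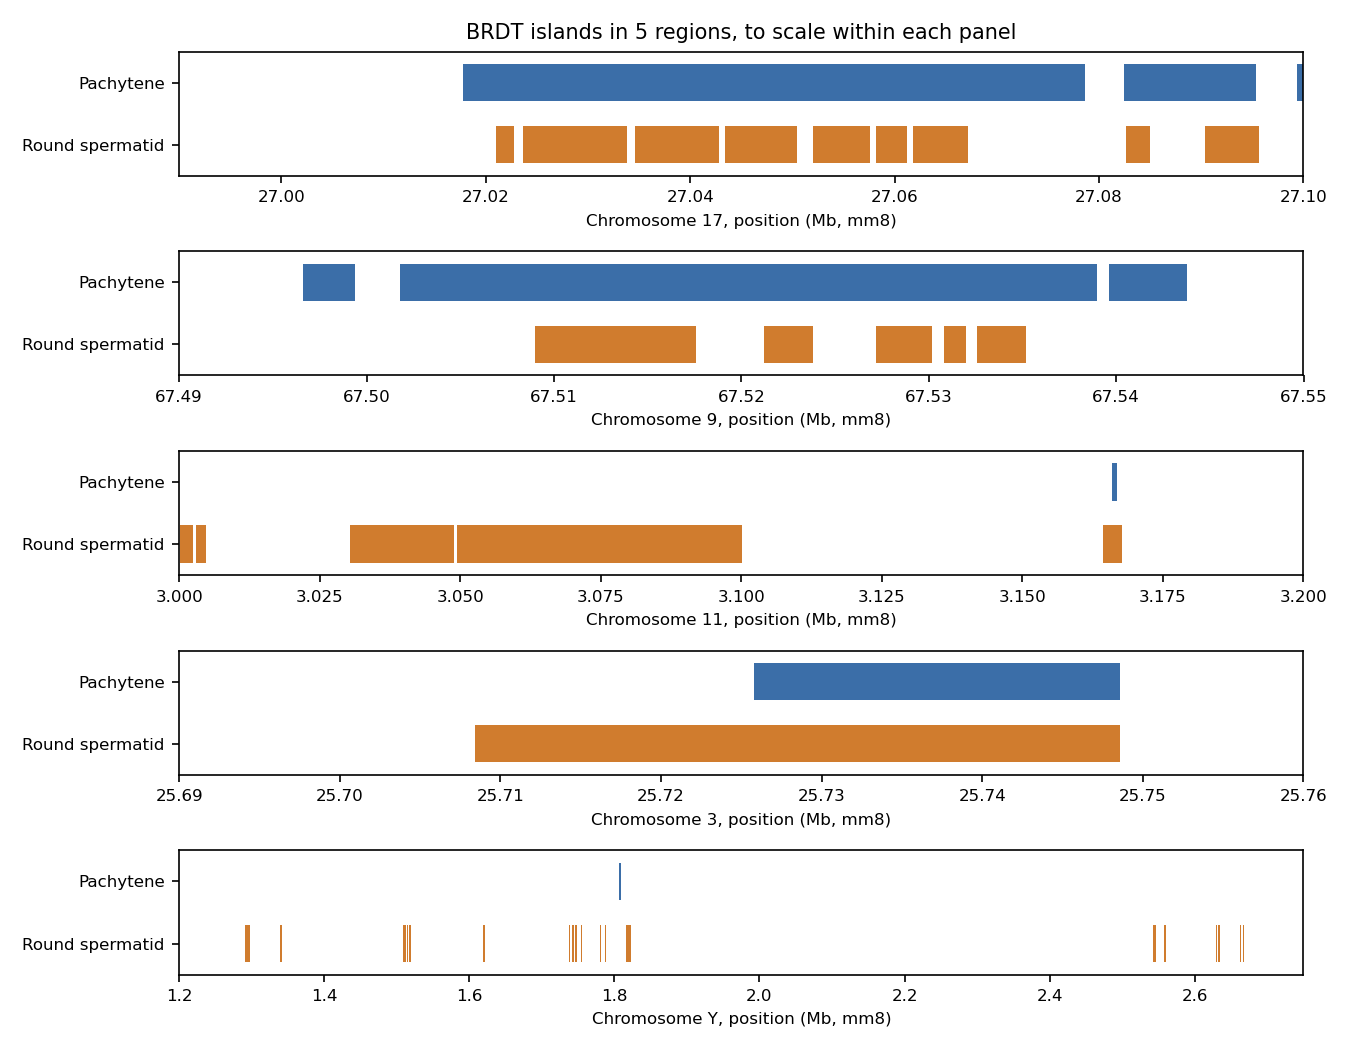
Positions of BRDT islands (bars; x axes in Mb on mm8) in pachytene spermatocytes (blue) and round spermatids (orange) in regions of chromosomes 17, 9, 11, 3 and Y. The 60.8 kb pachytene island on chromosome 17 faces 7 round spermatid islands, the 50.8 kb island on chromosome 11 has no pachytene island beside it, and Y holds 23 round spermatid islands and 1 pachytene island.

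BRDT islands were sparse on the X chromosome in both stages. The sex chromosomes are transcriptionally silenced in pachytene spermatocytes, and they were set apart for this reason. X held 27 pachytene islands, or 0.495% of the list (95% interval 0.327 to 0.720), and 37 round spermatid islands, or 0.659% (95% interval 0.464 to 0.907). This came to 0.163 islands per Mb of X in pachytene spermatocytes against 2.22 per Mb of autosome, a density 13.6 times lower (95% interval 9.32 to 20.6, exact binomial test p = 6.03e-114). In round spermatids it was 0.224 against 2.27 per Mb, 10.2 times lower (95% interval 7.36 to 14.4, exact binomial test p = 4.03e-107). Chromosome 3, the sparsest autosome in both lists, still held 8.57 times the density of X in pachytene spermatocytes and 7.64 times in round spermatids. The share of X against autosomes was not shown to differ between the lists (odds ratio of round spermatid over pachytene 1.34, Fisher's exact test p = 0.262). Males carry a single X, so its DNA dose is below that of an autosome in both cell preparations. The binomial tests set X at its full span and, like the intervals, take islands as independent. They allow for neither the lower dose nor the clustering of islands, so their p-values overstate the certainty.

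On X, 6 islands of each list overlapped the other list. The widest pachytene islands lay from 6241401 to 6247000 (5.6 kb), from 6197801 to 6201800 and from 159056801 to 159060800 (both 4.0 kb). The widest round spermatid islands lay from 142511401 to 142521200 (9.8 kb), from 4796801 to 4801000 (4.2 kb) and from 120314401 to 120318400 (4.0 kb).

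The Y chromosome held 1 pachytene island and 23 round spermatid islands. The pachytene island lay from 1805801 to 1808600, 8 kb from the nearest round spermatid island. The round spermatid islands were 200 to 7200 bp wide (median 2000 bp) and lay between 1290201 and 2668200, in 3 groups separated by over 100 kb. They made up 0.409% of the list (95% interval 0.260 to 0.614) against 0.0183% of the pachytene list (95% interval 0.000464 to 0.102). The odds ratio against autosomes was 22.4 (Fisher's exact test, p = 3.06e-06). Counted as groups joined over gaps under 100 kb, Y held 3 against 1, and the difference no longer passed (odds ratio 2.81, Fisher's exact test p = 0.626). Among the 2726 widest pachytene and 2809 widest round spermatid islands it was 4 against 1 (odds ratio 3.89, Fisher's exact test p = 0.375). Without wide and clustered islands, a check added after the data were seen, it was 8 against 1 (odds ratio against all other chromosomes 8.47, Fisher's exact test p = 0.0184, adjusted p = 0.0644).

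The densest and the sparsest autosome were the same in both lists, while several chromosomes took different shares of the lists. Chromosome 11, a gene-rich chromosome, was the densest autosome in both, with 3.49 islands per Mb (95% interval 3.17 to 3.84) in pachytene spermatocytes and 3.12 (95% interval 2.81 to 3.45) in round spermatids. Chromosome 3 was the sparsest, with 1.40 and 1.71 per Mb. Of 21 chromosomes, 7 passed an adjusted p of 0.05 by Fisher's exact test, and 10 had an unadjusted p under 0.05. Chromosome 5 held 5.74% of pachytene and 7.65% of round spermatid islands (odds ratio 1.36, Fisher's exact test, adjusted p = 0.000681). Chromosomes 13 and 14 also held larger shares in round spermatids (odds ratios 1.31 and 1.33), as did Y. Chromosomes 8, 9 and 15 held larger shares in pachytene spermatocytes (odds ratios of round spermatid over pachytene 0.82, 0.80 and 0.76). Fisher's test takes neighbouring islands as independent. When the list labels were swapped by whole 1 Mb windows, a check added after the data were seen, 1 chromosome passed (chromosome 5, permutation test, adjusted p = 0.0462), and when islands closer than 100 kb were joined, 1 passed (chromosome 9, Fisher's exact test, adjusted p = 0.0463).

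**Figure D4:**
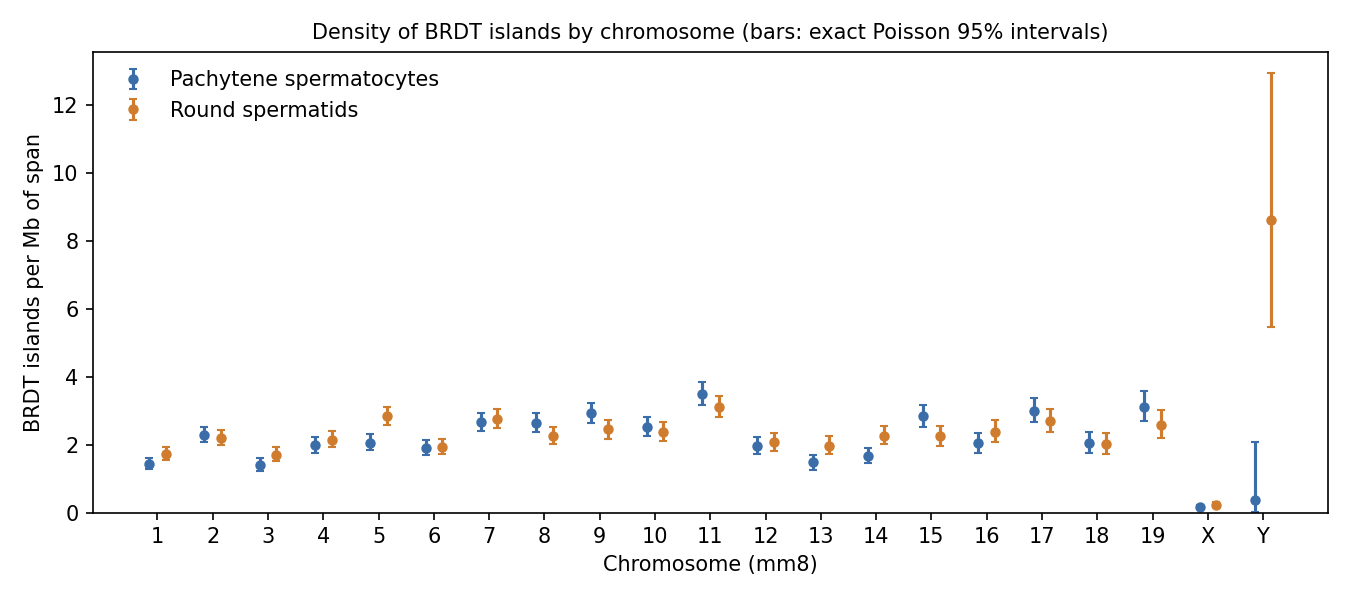
BRDT islands per Mb of chromosome span (y axis) for each chromosome (x axis) in pachytene spermatocytes (blue) and round spermatids (orange), with exact Poisson 95% intervals. X lies at 0.163 and 0.224 per Mb, below every autosome, and Y in round spermatids stands at 8.62 per Mb of the 2.67 Mb that its islands reach.

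At the scale of 1 Mb, windows with more BRDT islands in one list tended to hold more in the other. Across 2601 windows of the autosomes and X, the number of islands per window correlated between the lists (Spearman's rho 0.65, Pearson's r 0.63, circular-shift permutation p = 1e-05 for each, the smallest possible). Shifted windows gave a mean rho of 0.08, with the central 95% of shifts reaching up to 0.14. Windows are regions of 1 genome and not independent replicates. Both lists had islands in 1315 windows (50.6%) and neither in 665 (25.6%), while 222 held pachytene islands alone and 399 round spermatid islands alone. No autosome had an island in either list before 2999801. Windows of these stretches count among the 665 and enter the correlation, and how much they add to it was not tested.

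The window of chromosome 10 from 80 to 81 Mb held the most pachytene islands, 22, and 15 round spermatid islands. Next in pachytene spermatocytes were chromosome 8 from 122 to 123 Mb with 20 islands against 6 in round spermatids, chromosome 10 from 79 to 80 Mb with 19 against 8, and chromosome 15 from 76 to 77 Mb with 19 against 14. Chromosome 9 from 46 to 47 Mb followed with 18 against 8. In round spermatids, the window of chromosome 17 from 30 to 31 Mb led with 19 islands against 13 in pachytene spermatocytes. Chromosome 9 from 108 to 109 Mb held 15 against 11, and chromosome 5 from 38 to 39 Mb held 14 against 3. The windows of chromosome 10 from 80 to 81 Mb and chromosome 15 from 76 to 77 Mb were among the 5 fullest in both lists. No single window passed an adjusted p of 0.05 for a different share of the lists (exact binomial test, 1936 windows tested, 55 with an unadjusted p under 0.05, smallest adjusted p = 1). Chromosome 5 from 26 to 27 Mb held 0 pachytene and 10 round spermatid islands and still did not pass (exact binomial test, unadjusted p = 0.00197). Windows with few islands could hardly pass whatever their split, so the result does not show equal shares.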

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

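The tests on evenly placed islands and on island density were chosen after the values they bear on had been seen; joining of islands within 100 kb was set before the data were examined, but the bound by which its interval on Y was judged was chosen after its result was seen. The share of islands differed between the lists past an adjusted p of 0.05 (Fisher's exact test over 21 chromosomes) on chromosomes 5, 8, 9, 13, 14, 15 and Y. The odds ratios of round spermatid over pachytene were 1.36, 0.819, 0.802, 1.31, 1.33, 0.758 and 22.4 in that order.

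By odds ratio, the chromosome Y difference, 23 islands against 1, was the largest of these. Repeated counting of a few places is one candidate explanation: joined over gaps under 100 kb, the 23 islands form 3 groups, from 1290201 to 1342200, from 1509201 to 1822800 and from 2538001 to 2668200, with 2, 13 and 8 islands. The odds ratio went from 22.4 (95% interval 3.64 to 925) to 2.81 (95% interval 0.225 to 147). The odds ratio itself was lower after joining and the groups were few, 3 against 1; the joined interval includes both 1 and the value before joining, so repeated counting and a real difference cannot be told apart. Stage stays open as an explanation, as do mouse age and purification, which differed with it, and reads shared between repeated sequences of Y, which island positions cannot test.

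The shares of the autosomes moved with island density. Over the 19 autosomes, the odds ratio of round spermatid over pachytene fell with the mean density of the lists (Spearman's rho -0.70, permutation p = 0.00132; Pearson's r -0.66, permutation p = 0.00227; adjusted p = 0.00227 for both). Without chromosomes 11 and 3, the farthest from the median density, r was -0.64. Islands spread evenly along the genome, as background would be, may flatten a list in this way, and a fit on the autosomes would need 48.0% of round spermatid islands to lie evenly (95% bootstrap interval 37.4 to 70.1). For X, that part was placed evenly with X counted as a single copy, and the rest took the X share of the pachytene list. This put 1.83% of round spermatid islands on autosomes and X on X, against 0.661% observed (95% interval 0.466 to 0.910). The gap argues against even placement in proportion to DNA dose as the whole cause, but only as far as the fit holds. The pachytene shares enter both sides of the fit, so their counting error raises the fitted 48.0% and with it the expected 1.83%. The bootstrap does not allow for this, and the size of the effect was not measured. Islands must also pass the caller's threshold, and whether their number falls in proportion to dose was not tested. Background whose islands fall faster than dose stays open. Clusters counted several times stay open only in part: after joining over gaps under 100 kb, 1 autosome passed, and the odds ratios of chromosomes 5, 8, 13, 14 and 15 lay nearer to 1 (1.19, 0.973, 1.09, 1.21 and 0.905). Joining at 100 kb also merges islands that are neighbours by chance, as the median gaps are 144.8 kb (pachytene) and 168.6 kb (round spermatid). This happens more where a list is denser, so a move toward 1 does not by itself show clusters. The autosome that passed was chromosome 9. Its odds ratio lay farther from 1 than before joining (0.726, Fisher's exact test, adjusted p = 0.0463), which goes against repeated counting as the cause there. Without wide islands and islands within 5 kb of another, a test added after the data were seen, the odds ratios of chromosomes 5, 8, 9, 13, 14 and 15 stayed close to those of all islands (1.39, 0.843, 0.789, 1.32, 1.33 and 0.783), which argues against such close clusters as the whole cause, while wider clusters stay open. A difference between stages, ages or purifications was not tested.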

How the results depend on the processing

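Leaving out wide and clustered islands, splitting the files by their lines, swapping labels by windows and comparing mean widths were tests added after the data were seen. The overlap of the lists kept its direction and its side of the threshold under each alternative run, with folds over shifts of 7.04 (shifts of 20 kb to 1 Mb) to 25.5 (reciprocal overlap), permutation p = 0.0001 in each, the smallest that 10000 shifts can give. The window correlation also held, with rho of 0.54 (500 kb windows) to 0.83 (5 Mb windows). The chromosome Y odds ratio of 22.4 was 14.1 after joining islands closer than 5 kb and passed. It was 3.89 among the widest islands and 2.81 after joining within 100 kb, where it did not pass with 4 and 3 islands or groups against 1. Without wide and clustered islands it was 8.47 against all other chromosomes (8 against 1, Fisher's exact test p = 0.0184, adjusted p = 0.0644). The number of chromosomes with different shares went from 7 to 5 among the widest islands, of which 4 were among the 7. It was 1 after joining within 100 kb and 1 without wide and clustered islands. With labels swapped by windows it was also 1, but there the 2 occupied windows of Y cannot pass. None of the 7 changed direction among the widest islands, after joining or without wide and clustered islands. Swapping labels gives new p-values only and leaves the odds ratios as they were, so it cannot test direction. Without wide and clustered islands, chromosomes 9, 13, 14 and 15 had odds ratios of 0.789, 1.32, 1.33 and 0.783, close to those of all islands, with adjusted p of 0.0513 to 0.0566 (Fisher's exact test), and chromosome 8 had 0.843 (Fisher's exact test, adjusted p = 0.12). Joining and leaving out islands test fewer islands, and whether this alone ended the calls was not tested. The share of the round spermatid list on X was 0.455% by base pairs covered and 0.659% by islands. The width difference of shared islands passed for means, 187 and 168 bp, and not for medians, which differed by 0 bp, or by -200 bp (shared islands narrower) in round spermatids with reciprocal overlap (permutation p = 0.203), a sign opposite to that of the means; the cause was not tested. The permutation of means does not allow for wider islands being overlapped more often by chance. The widest islands number 2726 and 2809 by construction. Strength of shared islands and a stricter FDR were not run, since the lists give no value per island. No paired analysis was possible because each group has 1 library, and no replicate could be left out. Unknown read depth limits every comparison of number and width.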

Other observations

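The tests of file order in this part were chosen after the data were seen; the overlap without wide and clustered islands was also added then, but before its own result was seen, and that against regional density was set before. Some chains of neighbouring BRDT islands occurred in one list alone. Joined over gaps under 100 kb, 89 pachytene groups and 35 round spermatid groups held at least 6 islands, and 17 and 6 of them held no island of the other list. The fullest such pachytene group lay on chromosome 2 from 29850201 to 30239000 with 11 islands over 388.8 kb. Others with 7 islands lay on chromosome 1 from 169120401 to 169249000, chromosome 7 from 69755801 to 69809600, chromosome 8 from 13613201 to 13760200, chromosome 9 from 96592201 to 96812200 and chromosome 11 from 5883401 to 6175600. In round spermatids, the fullest were the 8 islands on Y from 2538001 to 2668200, and groups of 7 on chromosome 5 from 116935201 to 117145000 and on chromosome 7 from 30340401 to 30455600. These groups were chosen after their values were seen and were not tested. The variance of islands per 1 Mb window was 3.84 times the mean in the pachytene list and 2.85 times in the round spermatid list, and 1537 and 1714 windows held an island.

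The overlap of the lists was weighed against technical explanations. A shared preference for the same broad regions may raise it, but shifts of 20 kb to 1 Mb overlapped at most 178 islands against 948 observed, a fold of 7.04 over their mean. Wide or clustered islands that recur in both lists, such as those on chromosomes 3 and 1, were not the whole cause either: without islands over 10 kb and islands within 5 kb of another, 739 of 4911 pachytene islands were still overlapped, 12.8 times the shifted mean. A preference of both libraries for the same open or well-mapped sequence, and occupancy of the same places in both stages, stay open, since positions alone do not test them.

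The lines of the files are not in genomic order, and what they are ordered by is not stated. In the round spermatid file early lines tend to hold wider islands (Spearman's rho of line and width across islands, which are not independent replicates, -0.47), and in the pachytene file rho was 0.08. Islands in the earlier lines, with each file divided in the middle, were shared more often, 20.03% against 14.7% in the pachytene list (Fisher's exact test, p = 3.09e-07) and 18.3% against 16.0% in the round spermatid list (Fisher's exact test, p = 0.0234), so that the smaller difference was 2.31 percentage points. In the round spermatid file the wider islands of early lines would also overlap more often by chance. In the pachytene file rho was 0.08, but a rank correlation can miss a pattern that is not steady. Its median width was 3000 bp in the first 10% of lines and 3200 bp in the last 10%, against 2600 bp in the whole list. Whether width accounts for the difference in either file was not tested. An order of the lines by some measure of strength is a hypothesis for the greater sharing of early islands. Across the 974 overlapping pairs, however, no relation was detected between the line in one file and the line in the other (Spearman's rho 0.03, permutation p = 0.365; Pearson's r 0.04, permutation p = 0.183).

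The islands of X and Y tended to stand late in the round spermatid file and early in the pachytene file. In the round spermatid file their median line was 5259 of 5618 (60 islands, central 95% of random sets 2117 to 3500, permutation p = 2e-05, the smallest possible), with medians of 5063 on X and 5432 on Y. In the pachytene file the median was 1053 of 5452 (28 islands, central 95% of random sets 1769 to 3673, two-sided test against random sets, p = 0.0003). If late lines hold islands nearer the threshold, the round spermatid islands on the sex chromosomes may be among the less certain ones of that list. The median line of 5259 shows their place in the file but not what the order stands for. Late lines of that file also hold narrower islands, and its islands on X and Y had median widths of 2200 and 2000 bp, against 3200 bp in the whole list. The random sets were not matched for width, so a late place beyond that of narrow islands was not tested. They also took islands as independent. Joined over gaps under 100 kb, the 23 round spermatid islands on Y form 3 groups and the 37 on X form 27, so the p-values may overstate the certainty.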
